A study of Mus musculus with 163 samples.

How the data were processed

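The series holds 163 single hair cells from mouse cochleae at postnatal day 7 (P7), in 4 groups: 43 control outer hair cells (Ctrl OHC), 56 mutant outer hair cells (Exp OHC), 38 control inner hair cells (Ctrl IHC) and 26 mutant inner hair cells (Exp IHC). The 81 control and 82 mutant cells in the table equal the numbers of cells that the series text gives as having passed the authors' quality check, whose criteria are not stated. Per the labels, controls carried 1 Atoh1 allele with a tdTomato insertion, and mutants carried a Cre insertion in 1 Atoh1 allele, a tdTomato insertion in the other, and 2 floxed Rbm24 alleles. Cre and the modified second Atoh1 allele therefore differ between the groups together with Rbm24. Per the labels' protocols, cochleae were digested with papain, DNase, a protease and dispase and triturated, red fluorescent cells were picked by hand, and full-length cDNA was made with a Smart-Seq kit and tagmented. The protocol text calls the picked cells endogenous IHCs and iOHCs, a term (commonly for induced OHCs) that the design and the group labels do not use. The sources do not say how a picked cell was assigned to the IHC or OHC group, so known markers of either type check the labels and are no finding.

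The deposited values are raw read counts per gene and cell, without molecular identifiers. Per the submitters' processing notes, HISAT2 2.2.1, SAMtools and featureCounts 2.0.1 were used with the mm10 build. The annotation release, the strand setting and the treatment of reads shared by genes are not given in the sources. The table has 55291 genes, of which 55034 (99.5%) matched an identifier in the GENCODE annotation of GRCm38 (the same build as mm10), from which symbols and coordinates were taken. The other 257 identifiers held 0.0128% of all counts. No pair of cells had identical columns. As a check for repeated libraries, the counts of the 2000 highest genes were compared between all pairs of cells of a group, and the smallest chi-squared per degree of freedom was 275, 493, 283 and 489 in Ctrl OHC, Exp OHC, Ctrl IHC and Exp IHC.

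No label names the animal a cell came from, so each group is 1 sample, and cells are not replicates. No test, p-value or number of changed genes was computed. Counts were summed over the cells of a group and divided by the group's total to give counts per 1000000 (CPM). Groups were compared by the log2 ratio of CPM with an exact conditional binomial (Clopper-Pearson) 95% interval, and levels have an exact Poisson interval. The share of cells with a gene counts cells at 10 CPM or more and has an exact binomial 95% interval, or, where it is 0, the limit of 3 counts given below. Reads without molecular identifiers are not independent molecules, so all these intervals cover counting error only, and not the spread between animals. Where 1 sum was 0, the ratio was taken against a floor of 3 counts over the group and is printed as a bound. With 1 to 3 counts, the ratio has its counting interval. No ratio is given where both sums are at or under the floor. Summed totals were 4.00e+08 counts in Ctrl OHC, 7.20e+08 in Exp OHC, 3.49e+08 in Ctrl IHC and 3.65e+08 in Exp IHC. At these depths a level of 10 CPM has a counting interval of 9.69 to 10.3, 9.77 to 10.2, 9.67 to 10.3 and 9.68 to 10.3 CPM. The floor of 3 counts is 0.00751, 0.00416, 0.00861 and 0.00822 CPM in the same order. A share of 0 cells allows up to 6.98%, 5.36%, 7.89% and 11.5% by the rule of 3 counts.

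The comparisons, the gene lists, the rule for naming genes and the main set of alternative settings were fixed before the data were examined. The 3 comparisons were Exp OHC against Ctrl OHC, Exp IHC against Ctrl IHC, and Ctrl OHC against Ctrl IHC. In addition, the genotype ratio in OHCs minus that in IHCs was taken as a difference that was not tested. The 16 lists of hair cell biology were OHC genes, IHC genes, hair cell identity, neurogenic and neuroendocrine genes, hair bundle, mechanotransduction complex, ribbon synapse and exocytosis, ion channels and pumps, p53 targets, apoptosis machinery, integrated stress and unfolded protein response, immediate early and dissociation response, nuclear oxidative phosphorylation, mitochondrially encoded genes, splicing regulators, and cell cycle. The 7 lists of other cells were supporting cell, glia, neuron, mesenchyme, erythroid, immune and endothelial genes. A list was described by the median log2 ratio of its members at 1 CPM or more in the mean of the 2 groups, with a 95% order-statistic interval over members. For glia genes, with 5 members or fewer, the range over members stands in its place. Beside it stands the percentile of that median among 10000 random lists of the same size matched on expression in 20 bins, as a description. Members are not independent, and the percentile is no test. Genes enriched in either cell type were the 100 with the largest ratio each way between odd-numbered Ctrl OHCs and Ctrl IHCs, at 20 CPM or more and in 50% or more of the cells of the higher group. Their genotype ratio was taken from the even-numbered control cells, 21 OHCs and 19 IHCs. The plan was to use the members at 1 CPM or more in the mean of the 2 groups. That limit would keep genes close to absent in controls only where mutants have them. In its place all 100 genes of a set were used, with 0.5 counts added to each sum. After the data were seen, the sets were also chosen in control cells of 1 sex and measured in all cells of the other.

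Genes were named by a rule of size. It took Rbm24, Insm1 and Atoh1, and up to 4 members of each of the 16 lists with the largest ratios among members at 10 CPM or more in the higher group. It also took, per genotype comparison, the 12 highest and 12 lowest ratios among genes with 20 CPM or more and 50% or more of the cells in the higher group. These genes also had to keep their direction in the mean of CPM over cells and in the share of cells. Between the control groups 10 genes each way were taken, and up to 6 genes each way with ratios of 2-fold or more in opposite directions in OHCs and IHCs. The choice by size left out mitochondrially encoded and ribosomal protein genes, spike-ins and predicted gene names. Of sex-linked genes it left out only Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y. Vegfd and Dkc1, which the rule took, lie on the X chromosome. Named genes outside this rule are members of the fixed lists, or are said to have been chosen after their values were seen. The rule gives more genes than the text describes, and the text gives all those chosen by size and up to 4 of each list. Some genes that the rule takes are not reported here, among them 1 with opposite directions in the 2 cell types.

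These alternatives were equal weight for each cell, edgeR TMM factors in place of totals, thinning of each cell to 1000000 counts, leaving out cells beyond 3 median absolute deviations in depth, genes detected or mitochondrial share, leaving out the highest cell of each group, totals without mitochondrially encoded genes, other limits on list members, and other detection thresholds. After the data were seen, 5 alternatives were added: only cells with Y-linked transcripts and without Xist, only cells with Xist and without Y-linked transcripts, leaving out cells with 50 CPM or more for the sum of 5 supporting cell genes (Gjb2, Gjb6, Fabp7, Tectb, Otog), only cells under 40 CPM for the pseudogene Gm15772, and only cells at 40 CPM or more for it. Axonemal gene families were also chosen after the data were seen. Cells were not clustered, no doublet caller was run on hand-picked cells, and no cell was left out of the comparisons themselves. Transcripts of tdTomato and Cre are not in the mm10 build and were not measured.

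The calculation was tested on simulated counts with 200 genes changed by known folds of 2, 4, 8 or 16. The 95% intervals covered the simulated ratio for 94.8% of 14156 genes with the OHC groups, 95.2% of 14177 genes with the IHC groups and 95.4% of 14177 genes with the control groups. The direction was right for 100% of the changed genes at each fold in each of the 3 comparisons. All simulated cells of a group were Poisson draws from 1 profile, without the spread between real cells. These results therefore check the arithmetic only, and not how well the intervals cover real differences. The list percentile was tested on independent random normal values in place of ratios from counts. There a raised list reached percentiles of 100, 99.95 and 99.5, and of 300 lists of unchanged genes 12, 23 and 10 lay outside the central 95%. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.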

Results

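Full-length cDNA reads of 163 hair cells from P7 mouse cochleae were compared between controls and animals in which the RNA-binding protein gene Rbm24 was deleted with an Atoh1-driven Cre. There were 43 Ctrl OHCs, 56 Exp OHCs, 38 Ctrl IHCs and 26 Exp IHCs. Total counts per cell ranged from 5.47e+06 to 1.81e+07. The median was 9.09e+06 counts in Ctrl OHCs, 1.28e+07 in Exp OHCs, 8.67e+06 in Ctrl IHCs and 1.42e+07 in Exp IHCs. The median number of genes with a count was 9774 in Ctrl OHCs, 9698.5 in Exp OHCs, 10209 in Ctrl IHCs and 10236 in Exp IHCs. Mitochondrially encoded genes took a median of 6.04% of the counts in Ctrl OHCs and 4.36% in Exp OHCs, and 7.52% and 4.77% in the IHC groups. The 10 highest genes of a cell took a median of 10.3%, 8.73%, 11.0% and 8.28% in Ctrl OHC, Exp OHC, Ctrl IHC and Exp IHC. Cells with Y-linked transcripts and without Xist made up 74.4% of Ctrl OHCs, 28.6% of Exp OHCs, 68.4% of Ctrl IHCs and 26.9% of Exp IHCs, so the mix of male and female cells differed between the genotypes. By the pseudogene Gm15772, chosen after its values were seen, the cells of all 4 groups formed 2 sets, with 71 cells at 2.86 to 22.1 CPM and 92 cells at 61.4 to 768 CPM. The low set held 25 of 43 Ctrl OHCs, 16 of 56 Exp OHCs, 23 of 38 Ctrl IHCs and 7 of 26 Exp IHCs. Each cell with Xist lay in the high set, with 7 Ctrl OHCs and 3 Ctrl IHCs that had only Y-linked transcripts. The high set also held 6 Exp OHCs with neither, and 1 Ctrl OHC with Xist had Y-linked transcripts as well. In controls the sets by sex and by Gm15772 are thus partly confounded. In mutants the low set was the cells with Y-linked transcripts, so the 2 splits are not separate checks of the mutant cells. Ratios within the sets by sex stand beside Rbm24, Insm1 and the lists of OHC and IHC genes, and other ratios within these sets where they change a direction.

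Rbm24 (ENSMUSG00000038132.6, GRCm38 chromosome 13, 46418434 to 46431095, plus strand) was close to absent from both mutant groups. In OHCs it was at 315 CPM (95% interval 313 to 316) in controls and 0.212 CPM (0.180 to 0.249) in mutants, a 1481-fold difference (log2 ratio -10.53, -10.77 to -10.30). In IHCs it was at 431 CPM (428 to 433) in controls and 1.51 CPM (1.39 to 1.64) in mutants, a 285-fold difference (log2 ratio -8.15, -8.28 to -8.03). All 43 Ctrl OHCs and all 38 Ctrl IHCs had Rbm24 at 10 CPM or more. None of the 56 Exp OHCs did, which allows a share of up to 5.36% by the rule of 3 counts, and 2 of the 26 Exp IHCs did (7.69%, 0.946% to 25.1%). The lowest control cell had 78.8 CPM and the highest mutant cell 15.6 CPM, so Rbm24 sorted every cell by its genotype label. Among cells with Y-linked transcripts and among cells with Xist the log2 ratio was -12.78 and -10.28 in OHCs, and -6.97 and -9.18 in IHCs. Those 2 IHCs, at 15.6 and 11.6 CPM, set the mutant IHC level: without the highest cell of each group the IHC log2 ratio was -8.76.

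The series title asks how Rbm24 acts on OHC survival through Insm1, a zinc-finger repressor of differentiating OHCs and neurons, and on the hair bundle. In Exp OHCs, Insm1 (ENSMUSG00000068154.5, chromosome 2, 146221921 to 146225020, plus strand) was 4.91-fold higher than in Ctrl OHCs, at 18.7 CPM (18.4 to 19.0) against 3.81 CPM (3.63 to 4.01). The log2 ratio was 2.29 (2.22 to 2.37), and it was 2.16 among cells with Y-linked transcripts, 2.98 among cells with Xist, and 2.44 and 2.13 among cells low and high in Gm15772. Insm1 reached 10 CPM in 25 of 56 Exp OHCs (44.6%, 31.3% to 58.5%) and in 6 of 43 Ctrl OHCs (14.0%, 5.30% to 27.9%). Of the OHC genes 12 of 14 were lower in Exp OHCs, of the neurogenic list 7 of 8 were higher, and hair bundle genes as a list lay close to 0. The counts are per gene, so exon use and isoforms of these transcripts were not measured. The strip plots of single cells show Rbm24, Insm1 and 4 further genes in all 4 groups.

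**Figure D1:**
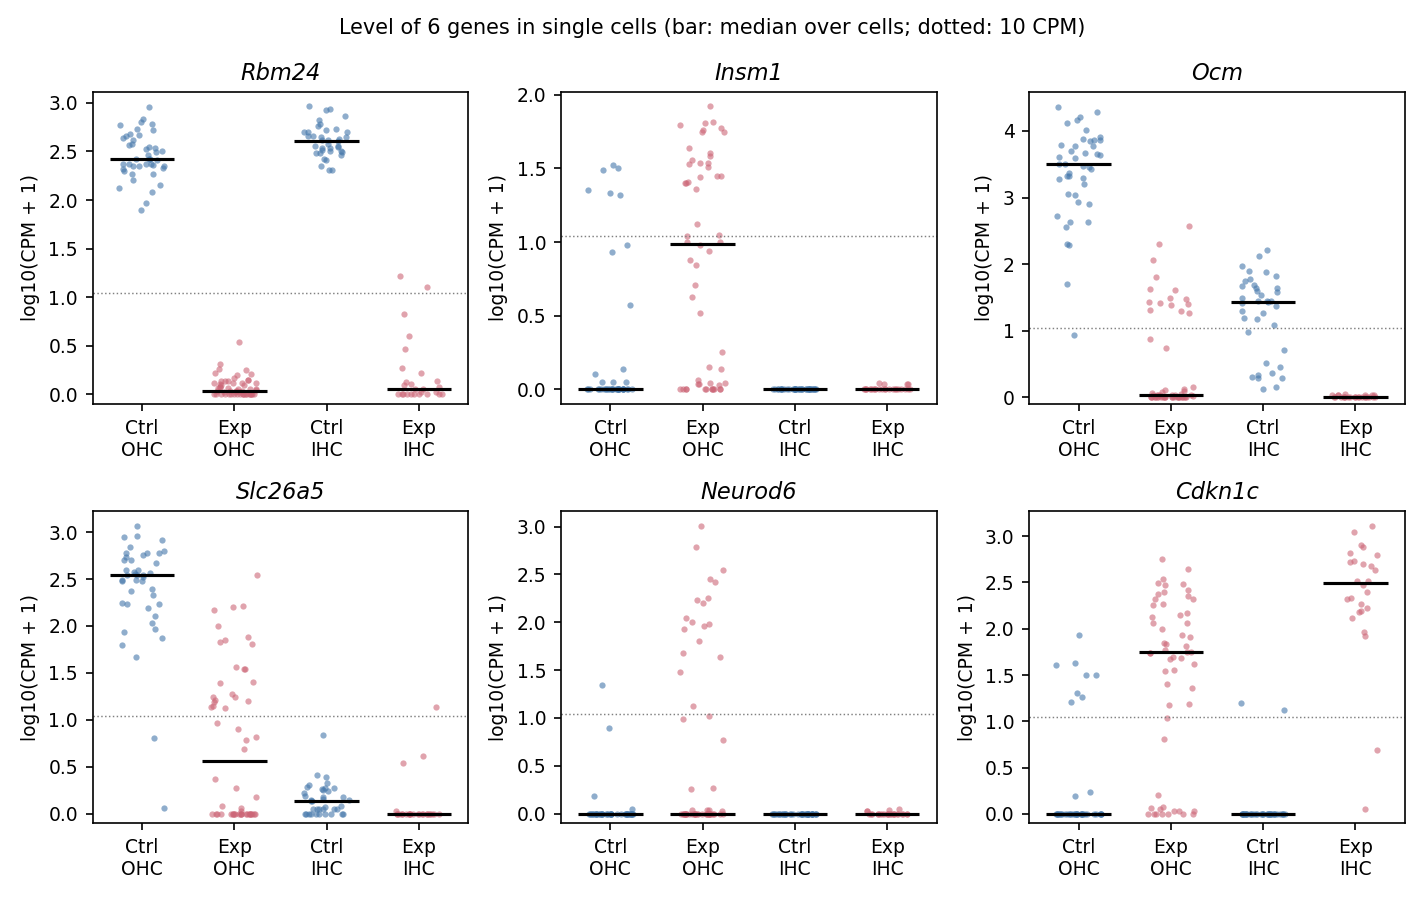
Level of Rbm24, Insm1, Ocm, Slc26a5, Neurod6 and Cdkn1c in each cell (points, log10 of CPM + 1) in the 4 groups, with bars at the median over cells and a dotted line at 10 CPM. Rbm24 is at 78.8 CPM or more in every control cell and at 15.6 CPM or less in every mutant cell, while Insm1 is at 10 CPM or more in 44.6% of Exp OHCs and 14.0% of Ctrl OHCs.

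Of 14 OHC genes, 12 were lower and 2 higher in Exp OHCs, with a median log2 ratio of -1.29 (-3.77 to -0.18, order-statistic interval over members), at percentile 0 among random lists of like expression. Ocm, which encodes the calcium buffer oncomodulin, went from 4952 to 18.6 CPM (267-fold) and from 97.7% to 26.8% of cells. Slc26a5, which encodes the OHC motor protein prestin, went from 376 to 27.5 CPM (13.7-fold) and from 95.3% to 41.1% of cells. Ppp1r17 went from 16.9 CPM to 1 count in all Exp OHCs. Ikzf2, a transcription factor of maturing OHCs, was at 174 and 39.9 CPM, Sri at 1134 and 155 CPM, and Aqp11 at 966 and 118 CPM. The nicotinic receptor genes Chrna9 and Chrna10 were within 2-fold, at 710.1 and 553 CPM and at 583 and 494 CPM. Against the list, Neurod6 was 136-fold higher (0.518 and 70.5 CPM, in 2.33% and 32.1% of cells) and Bcl11b 2.76-fold higher. A single Ctrl OHC held 65.2% of the control counts of Neurod6, and this cell had little of the OHC markers (Slc26a5 at 0.156 CPM, Ocm at 7.64 CPM and Ikzf2 at 0 CPM). Without the highest cell of each group the log2 ratio of Neurod6 was 8.06, against 7.09. The list median was -1.52 among cells with Y-linked transcripts and -0.98 among cells with Xist.

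Of the 9 measured IHC genes, 8 were lower and 1 was higher in Exp OHCs (median -1.60, -5.63 to -0.35, percentile 0), with -1.89 among cells with Y-linked transcripts and -1.72 among cells with Xist. The higher one was Tbx2 (0.546 and 2.15 CPM). Fgf8 (0.205 and 1.38 CPM), Dnajc5b (0.0476 and 1.87 CPM) and Brip1 (0.0200 and 0.174 CPM) of this list were also higher, but fell under the limit of 1 CPM in the mean of the groups. Several of the lower genes are also expressed in P7 OHCs: Calb2, which encodes calretinin, went from 2936 to 966 CPM, Cabp2 from 145 to 9.24 CPM, Atp2a3, a calcium pump of the endoplasmic reticulum, from 103 to 2.08 CPM, and Shtn1 from 25.4 to 4.54 CPM. Slc17a8, the vesicular glutamate transporter of IHCs, was at 6.16 CPM in Ctrl OHCs and 0.0472 CPM in Exp OHCs. Among hair cell identity genes 9 of 12 were higher (median 0.39, percentile 98.0). Atoh1, the factor that starts hair cell differentiation, was 3.45-fold higher (28.4 and 98.1 CPM), but each genotype carries different Atoh1 alleles. Ccer2 was 10.5-fold higher (142 and 1490 CPM) and Eya1 2.31-fold higher, while Gfi1, a zinc-finger factor needed for OHC survival, was 2.32-fold lower (199 and 85.8 CPM). Of 8 neurogenic and neuroendocrine genes 7 were higher (median 1.11, -1.09 to 2.37, percentile 99.8). The lists of neuron and glia genes, meant as markers of other cells, also had medians above 0 in these cells (2.17 and 1.67). Besides Insm1 the higher neurogenic genes included the prohormone convertase gene Pcsk1 (9.64 and 49.7 CPM, log2 ratio 2.37, and 2.97 without the highest cell of each group), Hes6 (45.9 and 167 CPM) and Nhlh1 (34.0 and 74.6 CPM).

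The hair bundle list had 21 members higher and 25 lower in Exp OHCs, 35 of 46 within 2-fold, and a median of -0.04 (-0.27 to 0.32, percentile 27.5), with 0.08 among cells with Xist. The actin bundler Lcp1 (plastin 2) was at 34.6 CPM in Ctrl OHCs and had 0 counts in Exp OHCs, at least 8319-fold lower. It reached 10 CPM in only 37.2% of Ctrl OHCs. The motor Myo3a was 5.67-fold higher (74.0 and 420 CPM), and taperin (Tprn) 3.58-fold higher. Among 11 mechanotransduction genes 7 were higher (median 0.39, percentile 96.1). Tmc2, the channel subunit of early postnatal hair cells, was 3.97-fold higher (14.0 and 55.7 CPM) and Tmc1, its successor, 1.86-fold lower (581 and 313 CPM). Harmonin (Ush1c) was 2.44-fold lower (230.2 and 94.4 CPM).

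Of 19 ribbon synapse and exocytosis genes 13 were higher (median 0.15, percentile 70.5), among them Syt1 (20.0 and 130 CPM), Rims2 (47.1 and 239 CPM) and Syt4 (7.18 and 29.9 CPM). Of 19 ion channel and pump genes 8 were higher and 11 lower (median -0.18, percentile 10.1). The ATP-gated channel P2rx2 went from 108 to 31.3 CPM. P2rx3 was 3.69-fold higher over all cells, though it reached 10 CPM in 14.3% of Exp OHCs, and its log2 ratio was -0.09 among cells with Xist. The Ctrl OHC that carried Neurod6 held 92.7% of the control counts of P2rx3, and without the highest cell of each group the log2 ratio was 4.93. Of 19 splicing regulators 12 were higher (median 0.22, percentile 80.0), with Rbfox3 7.88-fold higher (22.3 and 175 CPM) and Khdrbs2 4.50-fold higher.

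The 4 lists of death and stress genes had medians above 0 with members going both ways, and 3 of them fell below 0 in a part of the cells. Of 12 p53 targets 7 were higher (median 0.23, percentile 80.1, and -0.19 among cells low in Gm15772). Trp53inp1 was 3.89-fold lower, Btg2 2.69-fold higher (179 and 481 CPM) and Cdkn1a 1.07-fold higher. Of 12 apoptosis genes 7 were higher (median 0.15, percentile 69.5), and the median was -0.01 among cells with Y-linked transcripts, -0.05 among cells with Xist, and -0.03 and -0.18 among cells low and high in Gm15772. The caspase inhibitor Xiap was 2.39-fold lower, and the death effector Bax (51.8 and 96.6 CPM) was higher by less than 2-fold. Of 16 genes of the integrated stress and unfolded protein response 10 were higher (median 0.34, percentile 94.0). The serine synthesis gene Psat1 was 12.8-fold higher (76.9 and 985 CPM) and Atf4 2.43-fold higher (71.2 and 173 CPM). Of 15 immediate early and dissociation genes 11 were higher (median 0.42, percentile 90.6, and -0.51 among cells high in Gm15772), such as Ier2 (61.4 and 141 CPM). The heat shock gene Hspa1b was 7.45-fold lower (log2 ratio -2.90, and -3.79 without the highest cell of each group).

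Nuclear oxidative phosphorylation genes were slightly lower, 24 of 28 with none beyond 2-fold (median -0.24, -0.34 to -0.13, percentile 1.20), for example Cox5a (425 and 248 CPM) and Ndufa1 (802 and 496 CPM). All 13 mitochondrially encoded genes were lower (median -0.44, -0.83 to -0.31, percentile 1.03), but the median was 0.04 among cells with Xist. Of 12 cell cycle genes 9 were higher (median 0.41, percentile 89.9). The cyclin-dependent kinase inhibitor Cdkn1c was 18.8-fold higher (5.44 and 102 CPM), Cdkn2d 2.25-fold lower and Ccnd1 3.06-fold lower.

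The other lowest ratios by size belonged to Me3 (malic enzyme, 37.7 CPM and 4 counts, 6787-fold), Slc45a3 (52.7 and 0.0583 CPM), Zfp423 (129 and 0.447 CPM), Trim16 (75.7 and 0.668 CPM), Synj2 (132 and 2.05 CPM), Pxdc1 (268 and 4.80 CPM), Rn7sk (240 and 4.57 CPM), Car7 (carbonic anhydrase, 610 and 12.7 CPM) and Slc47a2 (56.8 and 1.35 CPM). The highest belonged to Igll1, with 0 counts in Ctrl OHCs and 283 CPM in 53.6% of Exp OHCs (at least 37695-fold), and Nek5, with 2 counts in Ctrl OHCs and 45.5 CPM in Exp OHCs (9099-fold, log2 ratio 13.15, 11.30 to 16.20). Fam92b (0.125 and 115 CPM), Pde1c (0.0651 and 46.3 CPM), the stress kinase gene Mapk10 (0.120 and 41.4 CPM), the growth factor gene Vegfd (0.103 and 33.9 CPM) and Sema3c (0.143 and 46.2 CPM) followed. Sstr2 (somatostatin receptor, 1.22 and 67.8 CPM), Coro2a (1.86 and 83.6 CPM), Abhd12b (5.25 and 235 CPM), Cntn1 (1.31 and 46.1 CPM) and the riboflavin transporter Slc52a3 (14.1 and 482 CPM) were also among the 12 highest. All 24 genes chosen by size kept their direction in the sets by sex and in those by Gm15772, in the former at log2 ratios of -13.78 to -4.69 for the lower and 3.08 to 13.67 for the higher ones, with sums of 0 taken at the floor of 3 counts. Single cells set the size of many of these ratios, and leaving out the highest cell of each group moved 17 of the 24 by over 1.5-fold, all of them farther from 0. The log2 ratio was then -13.62 for Trim16, -11.34 for Zfp423 and -9.11 for Synj2, against -6.83, -8.17 and -6.01, and -13.59 for Me3, -6.30 for Car7 and -6.00 for Slc47a2. Fam92b, Sstr2 and Sema3c then had 0 control counts, and their log2 ratios were at least 13.76, 13.00 and 12.47. The log2 ratio was 14.03 for Nek5, 10.85 for Pde1c, 10.49 for Mapk10, 10.14 for Vegfd, 7.85 for Coro2a, 6.80 for Cntn1, 6.49 for Abhd12b and 5.97 for Slc52a3.

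With 1 sample per group the spread between animals is unknown, and no difference was tested. The strand setting is not known, so reads of Ccer2, Trim16, Synj2, Sstr2 and P2rx3 cannot be separated from those of the genes overlapping them (Nfkbib, Fbxw10, Serac1, Slc39a11 and Ssrp1).

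In IHCs the same contrast asks how far the loss acts in the other hair cell type. Insm1 was at trace level there, with 0 counts in Ctrl IHCs and 4 counts in 4 of the Exp IHCs, and with 0 of 38 and 0 of 26 cells at 10 CPM. Genes of IHC identity were lower in Exp IHCs, most by less than 2-fold, and Cdkn1c and a set of ciliary genes had some of the largest higher ratios. Atoh1 was 1.64-fold higher (83.9 and 138 CPM).

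All 12 IHC genes were lower in Exp IHCs (median -0.86, -1.60 to -0.46, percentile 0), with -1.09 among cells with Y-linked transcripts and -0.97 among cells with Xist. Dnajc5b, a cysteine string protein gene, was 153-fold lower (143 and 0.938 CPM, log2 ratio -7.26), Slc7a14 4.92-fold lower (115 and 23.3 CPM), Calb2 3.02-fold lower (5358 and 1772 CPM) and Slc17a8 2.29-fold lower (252 and 110 CPM). A single Exp IHC held 97.7% of the mutant counts of Dnajc5b, and without the highest cell of each group its log2 ratio was -12.49. The other 8, among them Fgf8 (521 and 264 CPM) and Tbx2, a factor that sets IHC over OHC fate (186 and 154 CPM), were within 2-fold. Of 10 measured OHC genes 8 were lower (median -0.76, -1.69 to 0.10, percentile 0.06), with -1.56 among cells with Y-linked transcripts and -0.18 among cells with Xist. Ocm went from 34.2 CPM in 71.1% of Ctrl IHCs to 0.0219 CPM in none of 26 Exp IHCs (1561-fold), and Strip2 was 3.22-fold lower. Ocm was at 4952 and 18.6 CPM in Ctrl and Exp OHCs, and carry-over of OHC transcripts into picked IHCs was not tested. Of 12 identity genes 9 were higher (median 0.23, percentile 91.5, and -0.01 among cells high in Gm15772), with Ccer2 14.1-fold higher (160.3 and 2263 CPM) and Barhl1 1.77-fold higher (log2 ratio 0.82, and -0.07 among cells high in Gm15772). Of 7 neurogenic and neuroendocrine genes 6 were higher (median 0.86, -8.87 to 1.75, percentile 98.5), beside medians of 1.19 for neuron, 1.68 for glia and -9.63 for supporting cell genes in these cells, with Chga (86.0 and 253 CPM), Pcsk1 (8.71 and 29.3 CPM) and Hes6 (116 and 239 CPM) as examples.

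Of 46 hair bundle genes 31 were higher in Exp IHCs and 38 were within 2-fold (median 0.27, 0.06 to 0.42, percentile 99.5). Tprn was 3.50-fold and Tmc2 3.26-fold higher. Lcp1 went from 23.1 CPM, with 31.6% of Ctrl IHCs at 10 CPM or more, to 0 counts, at least 2810-fold lower. Of 11 mechanotransduction genes 9 were higher (median 0.32, percentile 92.0), such as protocadherin 15 (Pcdh15, 59.8 and 115 CPM). The ribbon synapse list had 10 genes higher and 9 lower, and its median of 0.03 (percentile 37.3) was -0.06 with TMM factors, -0.03 among cells with Xist and -0.24 among cells high in Gm15772. Within it Syt4 went from 4 counts to 20.4 CPM (log2 ratio 10.80, and 12.11 without the highest cell of each group) and Syt1 from 45.1 to 107 CPM. The ion channel list had 8 higher and 11 lower (median -0.05, percentile 25.4, but 0.05 to 0.07 within the sets by sex and by Gm15772), with the potassium channels Kcnma1 (72.2 and 28.0 CPM) and Kcnj13 (591 and 264 CPM) among the lower ones. Splicing regulators were split 11 and 11 (median 0.03, percentile 32.0, -0.06 with TMM factors, -0.16 among cells with Xist and -0.24 among cells high in Gm15772), with Khdrbs2 (17.9 and 90.8 CPM) and Rbfox3 (3.79-fold) higher.

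Of 13 p53 targets 7 were higher in Exp IHCs (median 0.34, percentile 84.6). Bbc3, which encodes the death inducer PUMA, went from 0.195 to 13.6 CPM and from 0 of 38 to 30.8% of 26 cells. Of 17 apoptosis genes 11 were higher (median 0.21, percentile 67.2), with Bax at 57.9 and 109 CPM and Bid 28.6-fold lower, and the median was -0.17 among cells with Y-linked transcripts and -0.19 among cells low in Gm15772. Of 19 stress response genes 11 were higher (median 0.21, percentile 73.8), such as Psat1 (373 and 969 CPM) and Atf4 (96.6 and 190.2 CPM), and the median was -0.02 among cells with Y-linked transcripts. Of 14 immediate early and dissociation genes 10 were higher (median 0.87, percentile 99.8), such as Dusp1 (15.6 and 80.5 CPM), Ier2 (42.0 and 164 CPM) and Egr1 (101 and 317 CPM). These genes respond to tissue digestion within minutes, and both genotypes were digested. Nuclear oxidative phosphorylation genes were lower in 24 of 28 (median -0.23, -0.33 to -0.16, percentile 0.79), and all 13 mitochondrially encoded genes were lower (median -0.70, -1.14 to -0.65, percentile 0). Of 13 cell cycle genes 5 were higher and 8 lower (median -0.51, -2.02 to 2.88, percentile 0.98), and the median was 0.15 among cells with Xist. Cdkn1c was 583-fold higher (0.671 and 391 CPM), in 92.3% of Exp IHCs, and Ccne1 4.55-fold lower. The control counts of Cdkn1c came from 2 of 38 cells, and its log2 ratio of 9.19 was at least 13.84 among cells with Xist, where controls had 0 counts, and 10.15 without the highest cell of each group. All mutant counts of Ccne1 came from 1 of 26 cells, and without the highest cells, with 0 mutant counts left, its log2 ratio was -10.63 or lower, against -2.19. Without the highest cells the log2 ratio was 7.33 for Bbc3, against 6.13, and -7.31 for Bid, against -4.84.

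The lowest ratios by size in IHCs were those of Ang4 (49.7 CPM and 0 counts, at least 6038-fold), Slc47a2 (20.8 CPM and 0 counts, at least 2530-fold), Ocm, Ccnd1 (cyclin D1, 45.6 and 0.0795 CPM), Rbm24, Dnajc5b and Atp6v1c2 (25.5 and 0.195 CPM). The phosphatase inhibitor Ppp1r1a (164 and 3.66 CPM), Cdon (33.8 and 1.20 CPM), Akr1b3 (92.1 and 3.62 CPM), the nuclear receptor Rorb (89.2 and 6.04 CPM) and Reep6 (385 and 33.7 CPM) followed. The highest were Igll1 (0 counts and 469 CPM, in 53.8% of Exp IHCs), Cfap161 (1 count and 56.8 CPM), Nacad (1 count and 39.7 CPM) and Lrrc26 (0 counts and 40.4 CPM, at least 4690-fold). Spag8 (0.0402 and 91.0 CPM), the natriuretic peptide gene Nppa (0.0143 and 23.7 CPM), Zbbx (0.0373 and 39.9 CPM), Cdkn1c and Slc52a3 (1.89 and 544 CPM) came next. The axonemal dynein Dnah9 (0.364 and 37.3 CPM), the radial spoke gene Rsph4a (0.453 and 36.3 CPM) and the tektin Tekt4 (0.640 and 46.8 CPM) completed the 12. All 24 kept their direction in the sets by sex and in those by Gm15772. Without the highest cell of each group the log2 ratio moved by over 1.5-fold for Rbm24, Dnajc5b and Cdkn1c, given above, and for 13 others. It was then -12.99 for Atp6v1c2, -6.40 for Cdon, -6.35 for Ppp1r1a and -4.87 for Rorb, against -7.03, -4.82, -5.49 and -3.88, and for Ccnd1, with 0 mutant counts left, -12.26 or lower, against -9.16. It was 13.32 for Dnah9, 7.92 for Tekt4 and 7.37 for Rsph4a, against 6.68, 6.19 and 6.32, and 11.86 for Spag8 and 9.93 for Slc52a3. Cfap161, Nacad and Zbbx had 0 control counts left and log2 ratios of at least 12.53, 11.96 and 11.97, against 14.27, 13.76 and 10.06.

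The plot of list medians shows both cell types side by side. As in OHCs, no difference was tested, and reads of Ccer2, Ccnd1, Atp6v1c2, Kcnj13 and Bid overlap those of Nfkbib, LTO1, Pdia6, Gigyf2 and Bcl2l13 on the genome. The heat shock and angiogenin genes Hspa1b and Ang4 belong to families of near-identical copies.

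**Figure D2:**
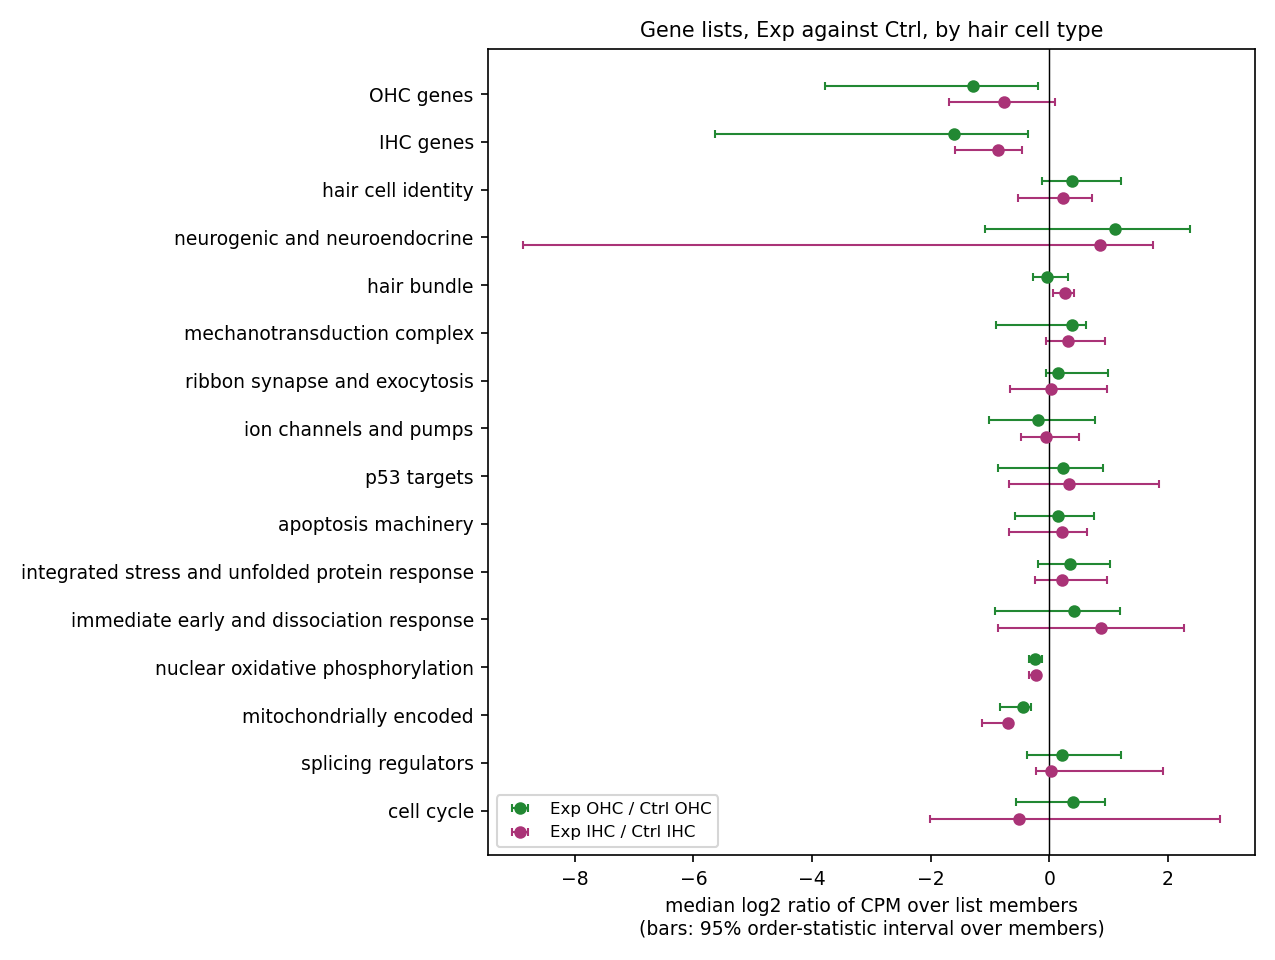
Median log2 ratio of CPM, Exp against Ctrl, over the members of each of 16 gene lists (points), in OHCs (green) and IHCs (purple), with bars for the 95% order-statistic interval over members. OHC genes lie at -1.29 in OHCs and -0.76 in IHCs, and hair bundle genes at -0.04 (0.08 among cells with Xist) and 0.27.

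Between control cells, OHCs and IHCs differed in the genes that define them, which checks the labels. All 13 measured OHC genes were higher in Ctrl OHCs (median 4.12, percentile 100) and all 12 IHC genes higher in Ctrl IHCs (median -3.67, percentile 0). Slc26a5 was at 376 CPM in Ctrl OHCs and 0.640 CPM in Ctrl IHCs, and Fgf8 at 0.205 and 521 CPM. The other genes highest in OHCs by size were the homeobox gene Emx1 (37.2 and 0.0143 CPM), Cacng2 (21.9 and 0.0115 CPM), Efna5 (153 and 0.129 CPM), the guidance receptor Robo2 (59.5 and 0.0545 CPM), Prcd, Zfp503, Calca (34.2 and 0.0545 CPM), Bmp6 and Ephx4. Those highest in IHCs were Hs3st4 (2 counts and 20.7 CPM), Dnajc5b, Ano4, Ang4, Brip1, Gcnt1, Fam19a3 (0.490 and 441 CPM), Tbx2 (0.546 and 186 CPM) and Tle2. Ribbon synapse genes were higher in Ctrl IHCs, 13 of 19 (median -0.48, percentile 0.03), and hair bundle genes higher in Ctrl OHCs, 29 of 46 (median 0.27, percentile 99.9). The remaining 12 lists of hair cell biology had medians between -0.31 (mitochondrially encoded, all 13 higher in IHCs) and 0.31 (mechanotransduction complex). Of the supporting cell genes 8 of 10 were higher in Ctrl IHCs (median -1.58, -5.46 to 1.69), as were 2 of 3 glia genes (median -0.59, range over members -1.43 to 5.20) and 4 of 6 neuron genes (median -1.42, -8.30 to 9.29). All 20 genes chosen by size kept their direction in the sets by sex and in those by Gm15772. Without the highest cell of each group the log2 ratio moved by over 1.5-fold for Hs3st4 (-12.82), Fam19a3 (-10.77), Tbx2 (-9.07), Tle2 (-8.20), Cacng2 (11.69), Bmp6 (9.87) and Ephx4 (9.67), each farther from 0.

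To see whether mutant cells kept these type differences, the 100 genes most enriched in either control type were chosen in odd-numbered cells and measured against the even-numbered ones. Of the OHC-enriched genes 70 were lower in Exp OHCs (median -0.66, -1.21 to -0.29), and of the IHC-enriched genes 65 were higher (median 0.87, 0.32 to 1.38). In Exp IHCs 65 of the IHC-enriched genes were lower (median -0.35, -0.52 to -0.17), and OHC-enriched genes were split 50 and 50. With the planned limit of 1 CPM, 60 of 90 IHC-enriched genes were higher in Exp OHCs (median 0.87, 0.34 to 1.37). With that limit 44 of 80 OHC-enriched genes were higher and 36 lower in Exp IHCs (median 0.12, -0.23 to 0.87). The other sets kept all 100 genes. Odd- and even-numbered control cells are not known to come from different animals, so these ratios are partly set by the choice of the genes. Choosing the genes in control cells of 1 sex and measuring them in cells of the other sex, a check added after the data were seen, keeps the animals apart. OHC-enriched genes in OHCs then had medians of -0.16 (-0.89 to 0.15) in cells with Y-linked transcripts and -0.48 (-1.23 to -0.21) in cells with Xist. IHC-enriched genes in OHCs had -0.43 (-1.29 to 0.13) and 0.88 (0.22 to 1.33), so their direction was not kept. In IHCs the medians were -0.35 (-0.93 to -0.03) and -0.01 (-0.29 to 0.33) for IHC-enriched genes, and -0.38 (-0.89 to 0.38) and -0.18 (-1.11 to 0.26) for OHC-enriched genes.

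Across 7338 genes at 20 CPM or more in the mean of the groups, the genotype ratios in OHCs and IHCs had a Pearson correlation of 0.603 and a Spearman correlation of 0.515, and 67.1% of the genes had the same sign. This relation is across genes, which are not independent replicates. Both ratios share the shift between genotypes in sex mix and in the sets by Gm15772, and OHCs and IHCs may come from the same animals. These may raise the correlation, which was not computed within the sets. The plot of the ratios in both cell types shows Rbm24 and Ocm low in both and Igll1, Cdkn1c, Slc52a3 and Ccer2 high in both.

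**Figure D3:**
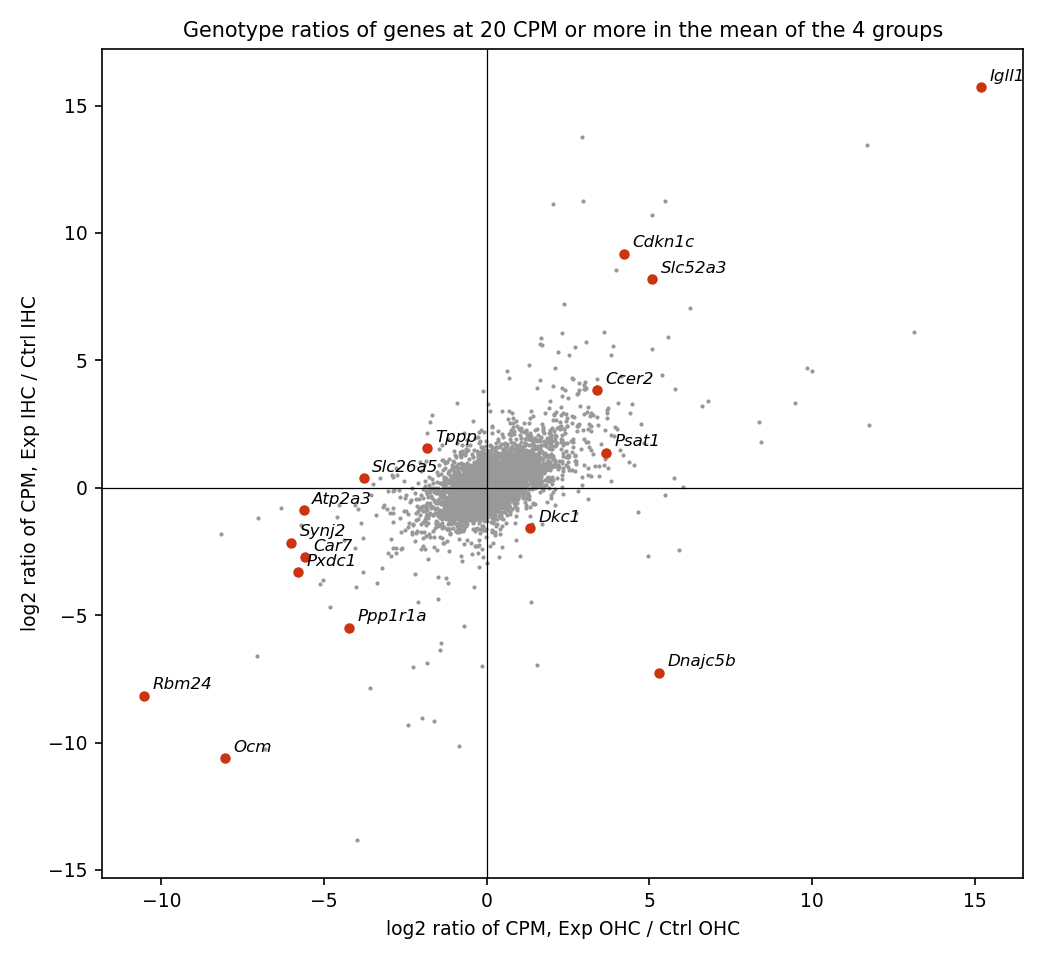
Log2 ratio of CPM, Exp against Ctrl, in OHCs (horizontal axis) and IHCs (vertical axis) for 7338 genes (points), with genes named in the text labelled. The ratios have a Pearson correlation of 0.603, and Rbm24 lies at -10.53 and -8.15.

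Transcripts of other cells were looked for with fixed lists. Supporting cell genes were lower in Exp IHCs (median -9.63, -12.4 to 0.41, percentile 0, 9 members), such as the connexin Gjb2 (29.9 and 0.00548 CPM), Fabp7 (39.3 CPM and 0 counts) and Tectb (79.7 and 0.00548 CPM). In OHCs the median was -0.33 (percentile 18.5), and 0.05 among cells with Y-linked transcripts. Cells with 50 CPM or more for the sum of 5 such genes numbered 7 Ctrl OHCs, 2 Exp OHCs, 9 Ctrl IHCs and 0 Exp IHCs, and without them the medians were 0.38 in OHCs and 1.60 in IHCs. Glial genes had a median of 1.67 in OHCs (percentile 97.4, 5 members) and 1.68 in IHCs (percentile 98.7, 3 members, and -2.06 among cells with Xist), led by the chaperone Cryab (117 and 833 CPM in OHCs) and by Cnp (104 and 330.2 CPM), while the myelin gene Mbp stayed at or under 1.12 CPM. Neuronal genes had a median of 2.17 in OHCs (percentile 99.9) and 1.19 in IHCs (percentile 99.1), with the neurofilament gene Nefm at 78.3 and 351 CPM in OHCs and 153 and 522 CPM in IHCs. Gap43, a growth cone protein gene, had 0 counts in Ctrl OHCs and 25.7 CPM in Exp OHCs. Cryab of the glia list and Calca of the neuron list were themselves among the genes most enriched in Ctrl OHCs. A higher median of these lists thus does not by itself show RNA of other cells. The mean log2(CPM + 1) over erythroid and over endothelial genes had a median of 0 in all 4 groups, and that of mesenchymal genes was at most 0.04. Immune genes had medians of 0.77, 0.95, 0.82 and 0.93 in Ctrl OHC, Exp OHC, Ctrl IHC and Exp IHC. Of these, C1qb was at 109, 267, 117 and 283 CPM, whereas C1qa and C1qc, made with it in macrophages, stayed at or under 1.26 CPM.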

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

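Genes with ratios of 2-fold or more in opposite directions in OHCs and IHCs were picked out by the rule fixed for naming genes, and no test was chosen after their values were seen. The difference between the 2 cell types was not tested for any of the 5 genes given here. Tppp, a tubulin polymerization-promoting protein gene, went from 45.5 to 12.7 CPM in OHCs and from 13.1 to 38.6 CPM in IHCs, and its genotype log2 ratio in OHCs minus that in IHCs was -3.40. Slc35e2 had a difference of -2.435, from 36.2 to 14.4 CPM and from 19.5 to 41.9 CPM. Ccdc74a had a difference of -2.28, from 115 to 48.2 CPM and from 73.8 to 150.2 CPM. Tmem30b, a flippase subunit gene, had a difference of -2.09, from 121 to 58.8 CPM and from 35.9 to 74.4 CPM. Dkc1, which encodes dyskerin, was the only one of the 5 higher in Exp OHCs, from 20.3 to 51.0 CPM, and lower in Exp IHCs, from 33.9 to 11.4 CPM (difference 2.90). In each of the 5 genes the direction in OHCs and in IHCs was the same among cells with Y-linked transcripts and among cells with Xist, though Tmem30b was at -0.28 in OHCs with Xist and 0.34 in IHCs with Y-linked transcripts.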

How the results depend on the processing

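The alternatives that keep only cells with Y-linked transcripts, only cells with Xist, only cells without supporting cell transcripts, or only cells low or only cells high in Gm15772 were chosen after the data were seen, and the others before. No paired analysis was possible because the labels name no animal or litter. A change of sign counts as a reversal where the ratio of a gene was 2-fold or more, or where a list median lay outside the central 95% of random lists. Of 2174 alternative values for 198 gene ratios, 2161 had the sign of the main value, 6 reversed, and 7 changed sign from a ratio of less than 2-fold. Apart from the reversals, 1444 lay outside the counting interval, which is narrow at this depth. Of 478 values for 40 list medians, 441 had the same sign, 5 reversed, and 32 changed sign from a median inside the central 95%. Apart from the reversals, 11 lay outside the interval over members. Of 64 values for 32 shares of cells, 23 lay outside the interval, and 8 went from 0 to above 0 or from above 0 to 0. TMM factors and totals without mitochondrial genes moved the median of all genes by at most -0.09 (log2). Leaving out cells beyond 3 median absolute deviations removed 1 Ctrl OHC and 4 Ctrl IHCs, and thinning removed 0 cells. For Rbm24 in OHCs the log2 ratio was -10.98 after thinning, -12.78 in cells with Y-linked transcripts, -10.28 in cells with Xist and -12.51 in cells low in Gm15772. For Rbm24 in IHCs it was -6.97 in cells with Y-linked transcripts, -9.18 in cells with Xist, -6.96 and -9.14 in cells low and high in Gm15772 and -8.76 without the highest cells. For Insm1 in OHCs it was 2.203 with equal weight per cell, 2.16 and 2.98 in cells with Y-linked transcripts and with Xist, 2.44 and 2.13 in cells low and high in Gm15772, 2.11 without cells with supporting cell transcripts and 2.49 without the highest cells. Insm1 in IHCs has no value after thinning, nor in cells with Y-linked transcripts, low in Gm15772 or without the highest cells, since both sums were at or under the floor. Reversed in cells with Xist were P2rx3 in OHCs (-0.0857), of which 1 cell held 92.7% of the control counts, mt-Atp8 in IHCs (1.16), and the list medians of mitochondrially encoded genes in OHCs (0.0389), cell cycle genes in IHCs (0.15) and glia genes in IHCs (-2.06). Reversed in cells with Y-linked transcripts were Zfp36 in OHCs (-0.41) and Zmat3 in IHCs (0.41). Zmat3 in IHCs also reversed in cells low in Gm15772 (0.51), and mt-Atp8 in IHCs in cells high in it (1.23). The 7 changes of sign from ratios of less than 2-fold were mt-Atp8 in OHCs, from -0.83 to 1.70 in cells with Xist and 1.66 in cells high in Gm15772, Insm1 in IHCs with Xist (-1.03), high in Gm15772 (-0.67) and without cells with supporting cell transcripts (-0.04), all against 0 control counts taken at the floor, so that its direction is not known, and, in cells high in Gm15772, Diablo in OHCs (-0.14) and Barhl1 in IHCs (-0.07). The supporting cell median in IHCs reversed without the cells that carry those transcripts (1.60), by construction, and the glia median in IHCs with 0.5 counts added to every member (-1.31), which lets in more members. The cause of the other reversals was not tested. Differences in a gene at or under 3 counts in both groups were not detectable at this depth.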

Other observations

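Tests of the OHC gene pattern and of the pseudogene counts were chosen only after the results were seen, and so were the axonemal families themselves and their test by Gm15772. The 3 other tests of these families were set before their results were seen. Motile cilium genes were higher in mutants of both cell types. Of 53 measured genes named Dnah, Dnai, Cfap, Tekt, Rsph or Drc, which build the axoneme, 50 were higher in Exp OHCs (median log2 ratio 1.74, 1.29 to 2.12, percentile 100), 40 of them by 2-fold or more. Of 52 in IHCs all were higher (median 2.27, 1.79 to 2.67, percentile 100), 41 of them by 2-fold or more. Of 63 genes with these names, those under 1 CPM in the mean of the 2 groups were left out. Genes close to absent in controls thus entered only where mutants had them, which may raise these counts and medians. Without the genes named for their size the medians were 1.71 and 2.18. Between Ctrl OHCs and Ctrl IHCs the median was -0.07.

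For the higher axonemal genes, a few cells carrying RNA of ciliated cells would leave most mutant cells at the control level, but 96.4% of Exp OHCs and all 26 Exp IHCs lay above the median control cell of their type. Above the highest control cell lay 33.9% of Exp OHCs and 96.2% of Exp IHCs. The different mix of sexes, or of the 2 sets by Gm15772, does not account for the whole pattern, since the smallest parts of the pooled values were medians of 1.11 (0.68 to 1.95) in OHCs with Xist and 1.67 (1.24 to 2.17) in IHCs high in Gm15772, though a partial contribution stays open. Scaling between the groups moved the medians by at most 0.0916. The genotype stays open as the source, and with it Cre, the second Atoh1 allele and the unnamed animals, which the design does not separate. One hypothesis, not tested, is that mutant cells may be less mature, since young cochlear hair cells still carry a kinocilium.

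For the lower OHC genes in Exp OHCs, the 7 members that were 2-fold or more lower were lower in each set by sex and by Gm15772. The nearest to 0 was Ikzf2, at -1.43 among cells with Xist and -1.66 among cells high in Gm15772. The different mix of these sets therefore does not alone account for the direction of these 7 genes. They were chosen as lower in these same cells, and the other members are not covered. In mutants the cells low in Gm15772 are those with Y-linked transcripts, so the 2 splits are not separate checks. IHCs among the cells labelled Exp OHC would bring IHC transcripts, but 4 genes restricted to IHCs were at a median of 0.517% of their level in Exp IHCs. Damage that raises the mitochondrial share is argued against by the median share in Exp OHCs minus that in Ctrl OHCs, -1.69 percentage points, which was -1.73 to -1.30 within the sets by sex and by Gm15772 and says nothing of other forms of damage. The median number of genes with a count was slightly lower in Exp OHCs, 9698.5 against 9774, although Exp OHCs had more counts per cell. Selective loss of the most mature OHCs would leave cells like the least mature controls. By the mean log2(CPM + 1) of these 7 genes 55.4% of Exp OHCs (41.5% to 68.7%) lay below every Ctrl OHC. With 6.98% allowed by 0 of 43 controls, such loss alone would have to remove 83.2% or more of the OHCs, whose number is not known. But the 7 genes were chosen as lower in these same cells, and the limits take cells as independent, so these values cannot exclude selective loss. It stays open, as do loss of Rbm24, Cre and the second Atoh1 allele, and the animals sampled. A delay of OHC maturation, which may give such values and was not tested, also stays open.

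Cells formed sets by counts in 3 pseudogenes chosen after their values were seen: in all 4 groups Gm15772 was either at 2.86 to 22.1 CPM or at 61.4 to 768 CPM, and the high set held each cell with Xist, with 7 Ctrl OHCs and 3 Ctrl IHCs that had only Y-linked transcripts and 6 Exp OHCs that had neither. Gm3375 was at 16.3 CPM or more in each Exp cell with Y-linked transcripts and at 8.49 CPM or less in every other Exp cell. Gm15459 was at 34.7 to 64.1 CPM in Exp IHCs with Y-linked transcripts and at 200 to 830 CPM in those with Xist. These ranges overlapped in Exp OHCs (28.9 to 112 and 68.1 to 962 CPM). In control cells with Xist, Gm15459 was at 30.1 to 72.6 CPM in OHCs and 18.3 to 66.75 CPM in IHCs. By these 2 pseudogenes mutants thus differed from controls within the sets by sex as well. Ratios within the sets may therefore still compare different animals or batches. For Gm3375, sex-linked expression alone is argued against, since no control cell with Y-linked transcripts had Gm3375 above 9.09 CPM. In the sample titles the high Gm15772 set was numbers 1 to 18 of Ctrl OHC, 17 to 56 of Exp OHC, 1 to 15 of Ctrl IHC and 8 to 26 of Exp IHC. The cell numbers thus followed the sets without a break. The sets may come from animals or litters with different strain sequence at these loci, or from different library batches, which no label gives. Both sexes occur in every group, so each group held cells of at least 2 animals.

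Igll1, a surrogate light chain gene of B cell precursors, had 0 counts in all 81 control cells and reached 10 CPM in 53.6% of Exp OHCs and 53.8% of Exp IHCs, in cells with Y-linked transcripts and in cells with Xist. Ocm was at 34.2 CPM in Ctrl IHCs, above 10 CPM in 71.1% of them, and at 4952 CPM in Ctrl OHCs, and carry-over between the types was not tested.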
